A study of Caenorhabditis elegans with 2 samples.

How the data were processed

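Anti-GFP ChIP-seq of strain RW12255 embryos was measured in 2 biological replicates of 1 group. The replicate numbers come from the labels, each replicate has 1 library, and no second condition, input or control list was analysed here. The authors deposited peak lists and no reads or counts: for each replicate a thresholded and a ranked list, and over both replicates a conservative thresholded list, another thresholded list and the 2 ranked lists behind them. Per the labels the coordinates are in ce11. Per the file descriptions deposited beside the lists, they were derived from filtered alignments and a control file, and the thresholded lists from 1 further file whose content is not described. The aligner, the peak caller, the version of the IDR program and the number of reads are not given in the sources used here. The depth per sample is therefore unknown, and the only error measures are the spread of the 2 replicates and counting intervals over peaks, regions and genes.

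The deposited signal is the value the authors' peak caller gave each peak. Its scaling, and how the control file enters it, are not given in the sources used here. The signal was used only to describe, rank and filter peaks within a list. The deposited score of the authors is an IDR score from 0 to 1000 that has a minimum of 830 in the thresholded lists. The ranked lists deposited by the authors give -log10 of the global IDR, and every peak of the thresholded lists was at 2.00 or more on that scale, so the authors' threshold was an IDR of 0.01. The ranked list over both replicates has a signal of the pooled replicates and 2 further signal columns. These 2 columns were taken as replicate 1 and replicate 2, because 74914 of 74916 and 41210 of 41210 peaks with shared intervals had values identical to those of the replicate's own ranked list. Medians and bins over both replicates use the pooled signal. Values given as mean ± SD (n = 2) use the 2 replicate columns, whose medians in the conservative list were 57.9 and 42.0 against 96.1 pooled.

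The conservative list was the main list, as fixed before the data were examined. Overlapping peaks were merged into regions, each placed at the summit of its strongest peak, and 94 of the 2538 regions held at least 2 peaks. Mitochondrial regions were left out of the comparisons because they have no chromosome or promoter background, and they are described apart. Gene models came from Ensembl release 115 on WBcel235, the same assembly as ce11. Coordinates are 1-based. Computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, and the replicate overlap was checked with bedtools 2.31.1, which gave the same 864 peaks.

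Peaks were called shared when they overlapped by at least 1 bp, and chance overlap came from 1000 uniform placements within chromosomes. A promoter ran from 1000 bp upstream to 200 bp downstream of a protein-coding gene start. The promoter share was tested against 10000 uniform placements, and densities on X against autosomes and on autosome centres against arms with 2-sided exact binomial tests. Feature classes were assigned in a fixed order, with tRNA genes and a 200 bp margin first, promoters next and other small RNA genes after them, and tested with exact binomial tests against the genome share. Signal and GC content were compared with 2-sided permutation tests of 100000 resamples. Gene lists and name families of at least 10 genes were tested with 2-sided Fisher's exact tests on the genes with a region in the promoter, against all nuclear protein-coding genes, or against all nuclear genes for RNA gene lists, with Benjamini-Hochberg adjustment and a threshold of 0.05. GC content and motifs were measured within 100 bp of promoter summits, with 10 control windows per region at the same distance from genes without a region. Intervals of shares are 95% Wilson intervals. Neighbouring genes share regions, so Fisher's tests over genes treat linked genes as independent. The lists were therefore also tested with 1000 circular shifts of all regions, whose smallest p is 0.002. Shifted regions lose the general preference for promoters, so a list can pass as enriched there through that preference alone.

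Named regions followed a rule fixed before the data were examined. It takes the nearest protein-coding gene within 1000 bp, or otherwise the position, for the 20 regions with the highest mean log2 signal over the replicates. It adds 4 members with the highest signal for each enriched list, up to 2 members with a region for each depleted list, flt-1, and up to 3 members for each tissue marker list. Of the 20 strongest regions 12 were mitochondrial, so the 20 strongest nuclear regions were added after the values were seen, as were the named members of gene name families.

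The tests were run on simulated data with known answers. These simulations were made after first results had been seen, and they changed no test fixed before. With an odds ratio of 4 planted over 19973 genes, 77.8% of the planted fixed protein-coding lists were recovered and 1.39% of the other lists were called. Planted were every 4th of the protein-coding lists with at least 20 genes, so recovery of smaller lists was not measured. Recovery of families was 23.8% from 20 genes to under 30, 45.5% from 30 to under 60 and 88.0% at 60 or more, so families that missed the threshold are not shown to lack regions. With nothing planted 0% of lists were called, and 4.67% of random placements had a promoter p under 0.05. Each simulated gene was drawn on its own, so these rates leave out the regions that neighbouring genes share. The random placements were tested against placements made in the same way, so that share checks the computation only. An enrichment with an odds ratio of 4 planted in piRNA genes alone made 8.88% of other lists pass, because these 15363 genes are part of the background of the RNA gene lists. That share was 0.0625% without piRNA genes in the background, and this background was added as an alternative. In the data piRNA genes were depleted (odds ratio 0.114), the opposite of the planted change, so these shares do not measure the effect there.

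Settings chosen for comparison before the data were examined were the other thresholded list, each replicate's own list, unmerged peaks, other promoter windows, denominators, boundaries, overlap rules, gene assignments, backgrounds and control windows. An IDR of at most 0.01 was among them, but it removes no peak. Alternatives chosen after seeing the data were an IDR of at most 0.0001, regions more than 500 bp from tRNA genes, peaks past the threshold that the conservative list leaves out, nuclear peaks only, circular shifts for lists, GC-matched controls and a background without piRNA genes.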

Results

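Binding of FLT-1 in mid-embryos of the nematode Caenorhabditis elegans was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq). By its label, strain RW12255 carries a flt-1 gene fused to TY1, EGFP and FLAG tags, and the fusion protein was recovered with an antibody against GFP. The gene is annotated now as baz-2 and encodes a bromodomain and PHD-finger chromatin protein of the BAZ2 family. Whole embryos were obtained by egg bleaching, have an age label of 1 hour and gave chromatin fragments of 200 to 800 bp. There was 1 group of 2 biological replicates and no other condition, so the comparisons available are between the replicates and between occupied sites and the rest of the genome. Peak lists without read counts were analysed, so the depth of each replicate is unknown and every interval given here covers the counting of peaks, regions or genes only.

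The replicates shared most of their called sites, and the sites combined over both made up 2520 nuclear regions. Replicate 1 had 1543 peaks and replicate 2 had 1142 peaks in their own lists. Of the replicate 2 peaks, 864 (75.7%, 95% Wilson interval 73.1 to 78.1) overlapped a replicate 1 peak by at least 1 bp, against a mean of 0.735% and a maximum of 1.61% over 1000 random placements. The reverse share was 56.4% (53.9 to 58.8), with 870 of the 1543 replicate 1 peaks overlapping. Random placements lack the preference of both lists for tRNA genes and promoters, so that preference alone could raise the overlap above them. Across the 2633 peaks of the conservative list, which compares both replicates, peak signal in replicate 1 and replicate 2 had a Pearson r of 0.856 on the log2 scale (bootstrap interval 0.840 to 0.868) and a Spearman rho of 0.625. These are correlations across peaks, which are not independent replicates, and r was 0.365 over all 96357 peaks ranked before the reproducibility threshold. The conservative list was selected for agreement between the replicates, so its r is partly set by that selection. The replicate 1 signal was higher at 2249 peaks (85.4%), by a median of 0.44 on the log2 scale with an SD of 0.43. The scaling of the signal is not given in the sources used here, so this offset is no measure of stronger binding. It also enters every SD over the 2 replicates given below, so a small SD there is no sign of closer agreement. The 2633 peaks merged into 2538 regions, of which 2520 lay on the nuclear chromosomes, with a median peak width of 296 bp and a median signal of 96.1 (interquartile range 78.7 to 142). A total of 868 of the 2633 peaks (32.97%) overlapped the own lists of both replicates and 1114 (42.3%) overlapped neither.

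FLT-1 regions were concentrated at tRNA genes and at promoters of protein-coding genes and were sparse in coding exons. Region summits lay in or within 200 bp of a tRNA gene in 274 cases, 10.9% of the 2520 regions (9.72 to 12.1) against 0.272% of the nuclear genome, a ratio of 39.9. Other small RNA genes outside promoters, with the same margin, took 83 regions, 3.29% (2.66 to 4.06) against 0.288% of the genome. Promoters outside the tRNA margin held 992 summits (39.4%) against 21.4% of the genome. Of the remaining classes, 18.5% of summits lay in introns against 30.3%, and 157 (6.23%) in coding exons against 19.7%. Intergenic sequence held 493 regions (19.6%) against 24.8%, and 3' UTRs held 26 (1.03%) against 2.35%. Each of these shares differed from its genome share by an exact binomial test adjusted over the 8 classes, with the adjusted p at most 2.13e-06. The share in 5' UTRs, 1.11% against 0.816%, missed the threshold (exact binomial, adjusted p = 0.119).

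**Figure D1:**
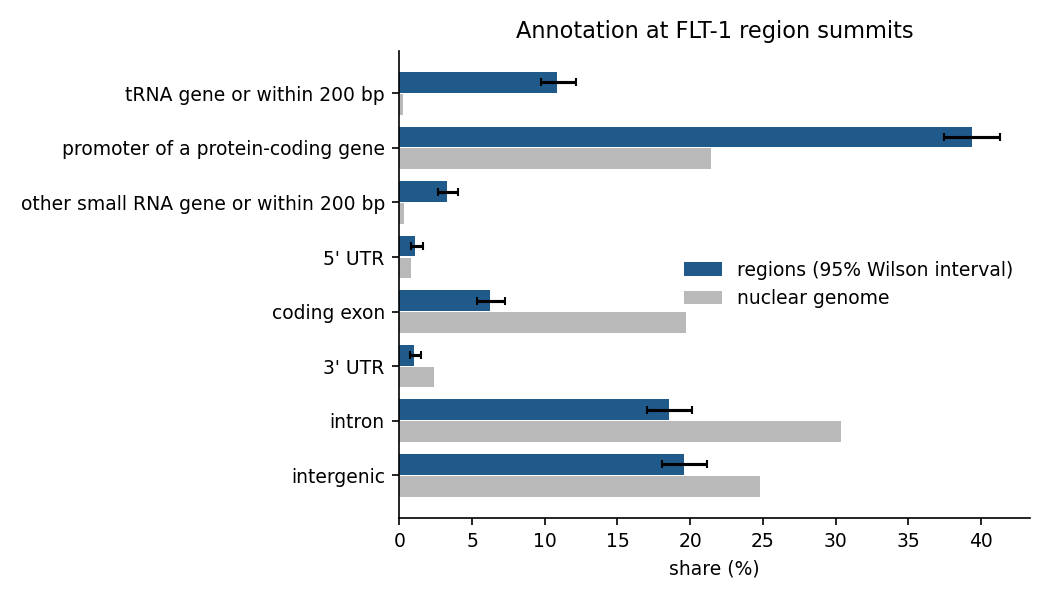
Share of the 2520 nuclear FLT-1 regions (blue, with 95% Wilson intervals) and of the nuclear genome (grey) in each annotation class, in percent. Summits in or near tRNA genes made up 10.9% of regions against 0.272% of the genome, and coding exons 6.23% against 19.7%.

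Counting also the promoter summits within the tRNA margin, 1043 of the 2520 summits (41.4%, 39.5 to 43.3) lay from 1000 bp upstream to 200 bp downstream of a protein-coding gene start. Random placement on the same chromosomes gave 21.1% ± 0.811 (SD over 10000 placements) with a maximum of 23.9%, and the 2-sided permutation p was 0.0001, the smallest that these placements can give. Most of the promoter summits were upstream of the start. There were 920 regions with a summit within 1000 bp upstream of the nearest start and 91 with a summit up to 200 bp downstream, and the median position of promoter summits was -193 bp. A region lay in the promoter of 1360 of 19973 protein-coding genes (6.81%), and 334 regions lay in promoters of at least 2 genes, so the gene at which FLT-1 sat is not resolved there.

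Among nuclear regions of the conservative list, signal was highest at small RNA genes. The median signal was 196 at tRNA genes (interquartile range 130.4 to 326) and 186 at other small RNA genes outside promoters (90.8 to 436). It was 106 at promoters (83.8 to 147), some of which also hold snoRNA, snRNA or microRNA genes, 90.1 in intergenic sequence, 87.4 in introns and 79.6 in coding exons. These are medians of the pooled signal. In the single replicates the promoter median was 60.7 in replicate 1 and 44.4 in replicate 2, the scale of the values with ± SD (n = 2) below. When the regions were ranked by signal into 10 bins of 252, the strongest bin held 109 regions near tRNA genes (43.3%) and the weakest held 2 (0.794%). The promoter share was 30.2% in the strongest bin and 49.2% to 50.8% in the next 3 bins. The median over all promoter regions was 108 against 91.9 over all other regions, a ratio of 1.17 with a permutation p of 1e-05, the smallest that 100000 resamples can give. That ratio did not hold in every list: it was 0.992 in the own list of replicate 2 (permutation p = 0.841) and 0.818 in the 378 nuclear regions with an irreproducible discovery rate (IDR) of at most 0.0001 (permutation p = 9e-05).

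**Figure D2:**
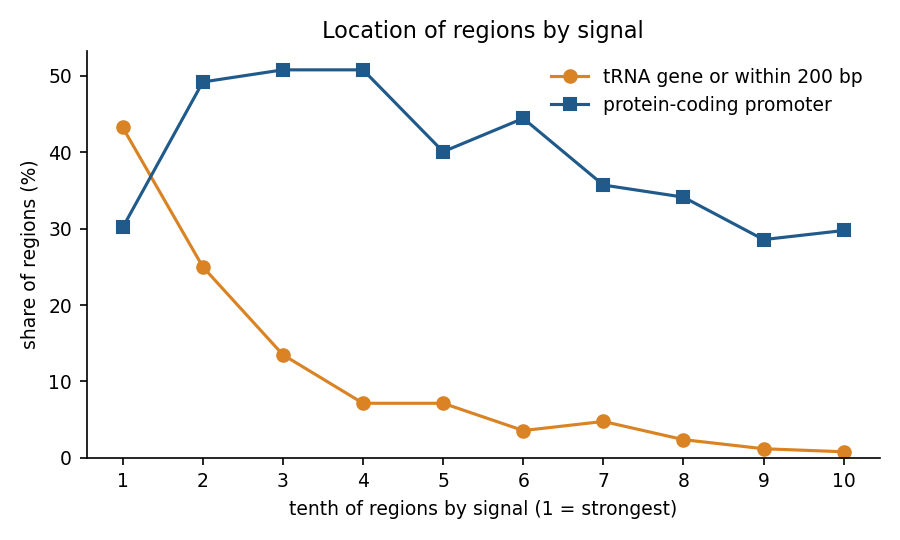
Share of regions, in percent, whose summit lies in or within 200 bp of a tRNA gene (orange) or in a protein-coding promoter outside that margin (blue), in 10 bins of 252 regions ranked by signal, with bin 1 the strongest. The tRNA share was 43.3% in the strongest bin and 0.794% in the weakest.

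Within the conservative list, most of the strongest nuclear regions were at genes for tRNAs and for snoRNAs, the guides of ribosomal RNA modification. This ranking holds for that list alone, since 14 of the 20 strongest nuclear peaks of the ranked list are not in it. Of its 20 strongest nuclear regions, 17 lay within 200 bp of a small RNA gene, 8 of them at tRNA genes and 8 at snoRNA genes. The strongest nuclear region in this list spanned V 12303468 to 12303787 (ce11) at the snoRNA gene C51F7.4, with a replicate signal of 707 ± 125 (SD, n = 2). The region at II 11960681 to 11960983 had a summit 62 bp upstream of the snoRNA gene W03C9.9 and a signal of 573 ± 130.1 (SD, n = 2). The region at IV 11025881 to 11026368 had a summit 85 bp from the microRNA gene cel-mir-51 and a signal of 434 ± 132 (SD, n = 2). At III 8043842 to 8044093, 522 bp upstream of K12H4.5, the signal was 485 ± 129.6 (SD, n = 2) and the nearest small RNA gene was 25440 bp away. The region at III 10461192 to 10461457, 66 bp upstream of the ataxin-2 gene atx-2, had 392 ± 110.2 (SD, n = 2) at 28847 bp from such a gene.

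Of 612 nuclear tRNA genes, 298 (48.7%, 44.8 to 52.6) had a region within 200 bp. The summit of the 274 regions at tRNA genes lay a median of 21 bp downstream of the gene start (interquartile range 11 to 32), inside the transcribed sequence, and 27 of them (9.85%) lay upstream. At snoRNA genes the position differed: 71 of 77 summits (92.2%) lay upstream, at a median of -45 bp (-55 to -27). The strongest tRNA region of the list, at X 13665433 to 13665749, had its summit 25 bp into the tRNA gene WBGene00000308 and a signal of 420.1 ± 92.0 (SD, n = 2). A difference between amino acid classes of tRNA genes was not detected, with a permutation p of 0.878 over 607 genes in 21 classes. By the promoter definition used for all genes, a region was assigned to 321 of 612 tRNA genes (52.5%), an odds ratio of 19.6 (16.7 to 23.1, adjusted Fisher p = 1.49e-225). The same test gave 113 of 346 snoRNA genes (odds ratio 7.98, adjusted Fisher p = 1.75e-51) and 40 of 261 microRNA genes (2.90, adjusted p = 1.38e-07). For genes of snRNAs, the RNAs of the splicing machinery and of trans-splicing, it gave 26 of 129 (4.03, adjusted Fisher p = 1.38e-07). Without piRNA genes, which are depleted, in the background these odds ratios were lower, at 13.7 for tRNA, 5.54 for snoRNA, 2.01 for microRNA and 2.80 for snRNA genes, and each call held. The odds ratio was 30.6 for tRNA and 13.9 for snoRNA genes at an IDR of at most 0.0001, 5.04 for snoRNA genes among genes with a ranked peak and 1.87 for microRNA genes with the single nearest gene start, where these calls held too.

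Among protein-coding genes, FLT-1 regions were enriched at promoters of the translation machinery, histones, chromatin regulators and nuclear genes of mitochondrial function. In the main setting, genes of cytosolic ribosomal proteins had the highest odds ratio among protein-coding lists, with a region at 41 of 81 (50.6%) against 6.63% of other protein-coding genes. Their odds ratio was 14.4 (9.30 to 22.4) and their adjusted p was 1.22e-25 by Fisher's exact test with Benjamini-Hochberg adjustment over 41 lists fixed before the data were examined. The odds ratio was 7.78 with the single nearest gene start and 9.07 among genes with a ranked peak, and the call held in both. Examples were rpl-3 (III 3867473 to 3867691, summit 273 bp upstream, signal 316 ± 56.5, SD, n = 2), rpl-15 (209 ± 17.1), rpl-20 (177 ± 28.9) and rps-19 (152 ± 3.85). Translation initiation and elongation factors had a region at 14 of 39 genes (odds ratio 7.73, 4.01 to 14.9, adjusted Fisher p = 4.41e-07). These included eif-3.C, a subunit of initiation factor eIF3, with 146 ± 37.9 (SD, n = 2), and the elongation factor genes eef-1A.1 with 100.4 ± 2.00 and eef-2 with 80.9 ± 9.74. The pooled signal was 202 at eef-1A.1 and 156 at eef-2. The eef-1A.1 region also lies 15 bp from the microRNA gene cel-mir-5549.

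Histone genes had a region at 35 of 84 (41.7%), an odds ratio of 10.01 (6.46 to 15.5, adjusted Fisher p = 1.12e-18). Neighbouring histone genes shared regions: a single region at I 9988832 to 9989123 with 207 ± 65.8 (SD, n = 2) served his-67 and his-68, and V 8898126 to 8898320 with 144 ± 74.05 served his-17 and his-18. Chromatin regulators had a region at 26 of 85 genes (odds ratio 6.13, 3.85 to 9.75, adjusted Fisher p = 1.87e-10). The strongest was 893 bp upstream of cbp-1, the p300/CBP acetyltransferase gene, at III 9765469 to 9765726 with 217 ± 56.8 (SD, n = 2). It was followed by swsn-3 of the SWI/SNF complex with 101 ± 5.94, the SET-domain methyltransferase gene set-16 with 92.2 ± 11.3 and the histone demethylase gene jmjd-1.2 with 90.7 ± 25.4. The pooled signal was 203 at swsn-3, 180 at set-16 and 198 at jmjd-1.2, above the pooled promoter median of 106. These genes were named for having the highest signal of the list, so this says nothing about the list as a whole. Splicing factors had a region at 13 of 49 genes (odds ratio 4.98, adjusted Fisher p = 4.87e-05), among them prp-19 with 158 ± 53.6 and snr-1 with 114 ± 42.3 (SD, n = 2).

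Respiratory chain and ATP synthase genes had a region at 20 of 70 (28.6%), an odds ratio of 5.54 (3.29 to 9.33, adjusted Fisher p = 1.10e-07). Members were ndua-2 of complex I with 138 ± 23.3 (SD, n = 2), the cytochrome oxidase genes cox-5B with 124 ± 37.9 and cox-6A with 121 ± 0.582, and atp-1 of ATP synthase with 113 ± 20.4. The cox-6A region overlaps the snRNA gene F54D8.7, and the ndua-2 region is shared with the chaperone gene dnj-29. Mitochondrial ribosomal proteins followed with 13 of 70 genes (3.14, adjusted Fisher p = 0.00191), led by mrpl-23 with 163 ± 28.9 (SD, n = 2), whose region lies 34 bp from the snoRNA gene T08B2.13. That call ended among genes with a ranked peak (1.96, adjusted Fisher p = 0.0943). Heat shock proteins had a region at 14 of 51 genes (5.22, adjusted Fisher p = 1.61e-05), including hsp-60 of the mitochondrial matrix with 153 ± 69.99 and hsp-3 of the endoplasmic reticulum with 122 ± 67.8 (SD, n = 2). Members also included the chaperone genes dnj-29 with 138 ± 23.3 and dnj-28 with 109 ± 39.1 (SD, n = 2). This list shares hsp-60, hsp-6 and dnj-10 with the mitochondrial stress response list, so the 2 calls are not independent. The mitochondrial stress response list passed with 4 of 15 genes, hsp-60, hsp-6, ubl-5 and dnj-10 (4.99, 1.59 to 15.7, adjusted Fisher p = 0.0311). That call ended in the own list of either replicate, with odds ratios of 1.54 in replicate 1 (adjusted Fisher p = 0.653) and 1.95 in replicate 2 (adjusted p = 0.634). It also ended with promoters from 500 bp upstream to 100 bp downstream (4.66, adjusted Fisher p = 0.0680) or from 2000 bp upstream (3.64, adjusted p = 0.0768), with the single nearest gene start (2.48, adjusted p = 0.371) and among genes with a ranked peak (2.90, adjusted p = 0.151). Cyclins, CDKs and mitotic genes had a region at 11 of 42 genes (4.89, adjusted Fisher p = 0.000215), such as pcn-1 with 60.01 ± 27.5 and cki-1 with 58.2 ± 18.4 (SD, n = 2). Their odds ratio was 2.28 in the own list of replicate 1 (adjusted Fisher p = 0.234) and 0.665 in that of replicate 2 (adjusted p = 1). Among the 378 regions with an IDR of at most 0.0001 the calls of 6 enriched lists ended. They were chromatin regulators (2.01, adjusted Fisher p = 0.788), splicing factors (3.55, adjusted p = 0.395), mitochondrial ribosomal proteins (1.203, adjusted p = 1), the mitochondrial stress response (5.94, adjusted p = 0.519), cyclins, CDKs and mitotic genes (0, adjusted p = 1) and microRNA genes (1.33, adjusted p = 0.936). Histones (6.52) and heat shock proteins (9.19) kept theirs there. Among genes with a ranked peak the odds ratio was 4.89 for translation factors, 3.43 for respiratory chain genes, 4.04 for chromatin regulators, 3.07 for splicing factors and 16.8 for histones, and each call held.

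**Figure D3:**
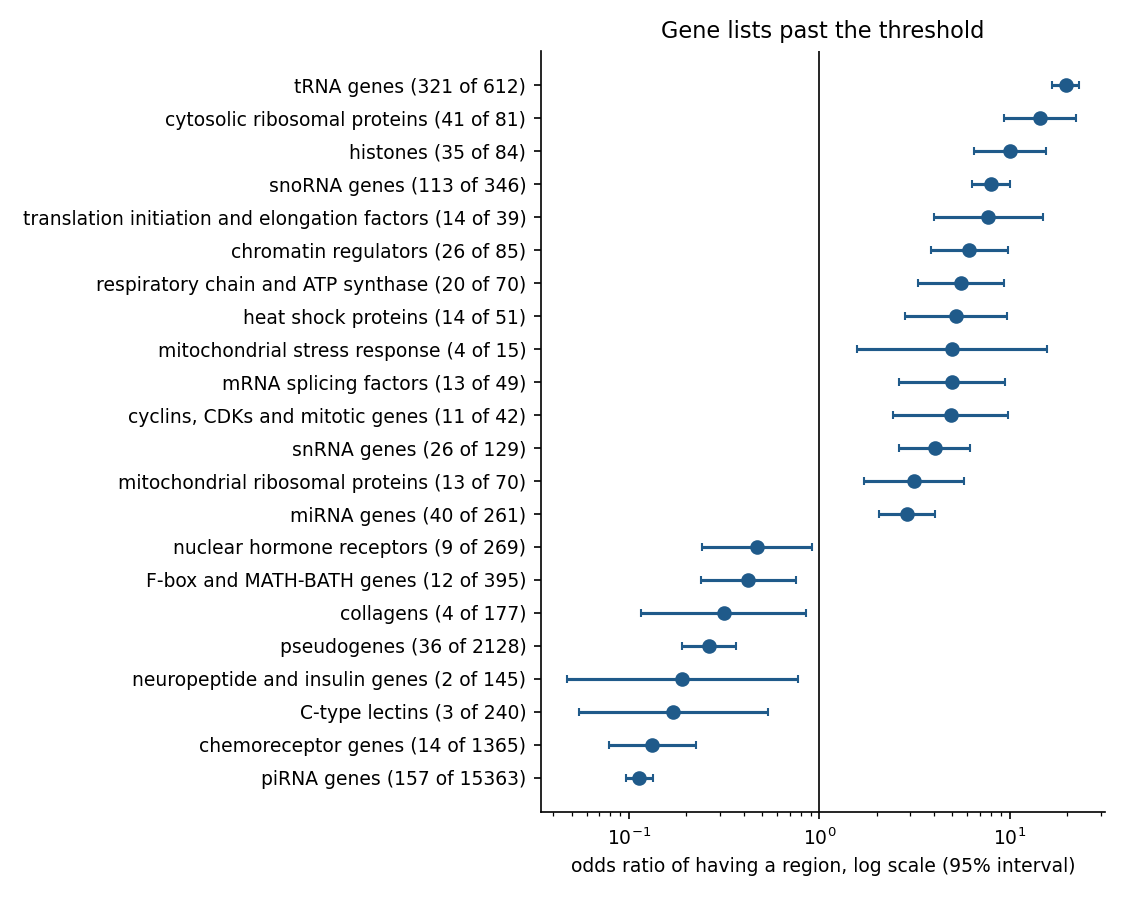
Odds ratio, on a log scale, of having an FLT-1 region in the promoter for the 22 fixed gene lists past an adjusted p of 0.05 by Fisher's exact test, with 95% intervals and the number of genes with a region. Values run from 0.114 for piRNA genes to 19.6 for tRNA genes.

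Regions were depleted at genes of chemoreceptors and piRNAs, at pseudogenes and at 5 smaller protein-coding lists. Chemoreceptor genes had a region at 14 of 1365 (1.03% against 7.23% of other protein-coding genes), an odds ratio of 0.133 (0.0783 to 0.226, adjusted Fisher p = 2.11e-25). The odds ratio was 0.285 among genes with a ranked peak and 0.350 at an IDR of at most 0.0001. The strongest chemoreceptor region, 615 bp upstream of sre-23 at I 8259431 to 8259694, had a summit 56 bp from the snoRNA gene ZK265.10 and a signal of 484 ± 77.8 (SD, n = 2). Genes of piRNAs, the small RNAs of germline silencing, had a region at 157 of 15363 (0.114, adjusted Fisher p = 3.15e-279) and pseudogenes at 36 of 2128 (0.263, adjusted p = 1.04e-21). For piRNA genes the odds ratio was 0.0715 in the own list of replicate 2 and ran from 0.0344 with the single nearest gene start to 0.221 among genes with a ranked peak. Depletion also passed for C-type lectins (3 of 240, odds ratio 0.171, adjusted Fisher p = 0.000215) and F-box and MATH-BATH genes (12 of 395, 0.424, adjusted p = 0.00367). It further passed for neuropeptide and insulin genes (2 of 145, 0.190, adjusted Fisher p = 0.00942), collagens (4 of 177, 0.314, adjusted p = 0.0212) and nuclear hormone receptors (9 of 269, 0.470, adjusted p = 0.0373). Against circularly shifted positions the depletions were smaller: 14 chemoreceptor genes against a mean of 31.1 (adjusted permutation p = 0.0145), 157 piRNA genes against 349.6 (adjusted p = 0.00546) and 36 pseudogenes against 55.3 (adjusted p = 0.0216). In each of the 5 smaller lists the count was not shown to differ from that at circularly shifted positions, with permutation p adjusted over the 41 lists from 0.438 to 1, so a depletion was shown against other genes but not against random positions. The regions assigned to clec-126, flp-23, col-185 and nhr-255 lie on tRNA genes. In the own list of replicate 1 the calls for F-box and MATH-BATH genes (0.671, adjusted Fisher p = 0.368), neuropeptide and insulin genes (0.300, adjusted p = 0.227) and collagens (0.496, adjusted p = 0.353) ended. In that of replicate 2 the calls ended for neuropeptide and insulin genes (0.380, adjusted Fisher p = 0.448), collagens (0.310, adjusted p = 0.200) and nuclear hormone receptors (0.305, adjusted p = 0.0650). All 5 calls ended at an IDR of at most 0.0001, with adjusted Fisher p from 0.873 to 1. Nuclear hormone receptors also lost theirs with the single nearest gene start (0.491, adjusted Fisher p = 0.0936) and among genes with a ranked peak (0.571, adjusted p = 0.237), and collagens turned with the single nearest gene start (1.07, adjusted p = 0.888). Calls held with other odds ratios in the other thresholded list for nuclear hormone receptors (0.295) and C-type lectins (0.275), and away from tRNA genes for neuropeptide and insulin genes (0.0988).

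No list of tissue markers passed the threshold, and nuclear hormone receptors were the only transcription factor list that did. Whole embryos hold all of these tissues, so the lists describe the genes and not the cells. Muscle markers had a region at 4 of 29 genes (odds ratio 2.19, adjusted Fisher p = 0.225), among them the actin gene act-4 with 51.8 ± 23.1 and unc-97 with 42.03 ± 0.782 (SD, n = 2). Germ line markers had one at 4 of 44 (1.37, adjusted Fisher p = 0.693), where mex-1, an RNA-binding protein gene, had 146 ± 41.3 and spn-4 had 56.03 ± 1.89 (SD, n = 2). Neuron markers had one at 3 of 44 (1.00, adjusted Fisher p = 1), with syd-2 at 63.4 ± 29.5 and unc-40, the netrin receptor gene, at 58.3 ± 12.9 (SD, n = 2). The intestine list had 1 of 31 (erm-1, adjusted Fisher p = 0.869), the pharynx list 1 of 22 (marg-1, adjusted p = 1) and the epidermis list 0 of 31 (adjusted p = 0.409). The Hox cluster had 0 of 6 genes (adjusted Fisher p = 1), T-box genes 0 of 21 (adjusted p = 0.580) and forkhead genes 0 of 15 (adjusted p = 0.769). A count of 0 is the lowest possible, and in these lists and the epidermis list it gave a Fisher p of 0.269 to 1 before adjustment, so depletion could not have been called there. Enrichment is not excluded in small lists either, as the interval of 0.762 to 6.31 for muscle markers shows. Homeobox genes had 7 of 99 (adjusted Fisher p = 0.958), bHLH genes 3 of 39 (adjusted p = 0.875) and GATA factor genes 2 of 13 (adjusted p = 0.361). Aminoacyl-tRNA synthetases, whose products charge tRNAs, had 5 of 32 (odds ratio 2.54, 0.977 to 6.61, adjusted Fisher p = 0.113) and proteasome subunits 3 of 33 (adjusted p = 0.669). The remaining lists also missed the threshold: Wnt and Notch signalling (2 of 39, adjusted Fisher p = 1), dosage compensation and condensin (1 of 17, adjusted p = 1), cilia genes (1 of 40, adjusted p = 0.690), major sperm proteins (1 of 48, adjusted p = 0.407) and lincRNA genes (14 of 194, adjusted p = 0.628). Against circularly shifted positions, however, aminoacyl-tRNA synthetases passed with 5 genes against a mean of 0.947 (adjusted permutation p = 0.0182) and lincRNA genes with 14 against 5.80 (adjusted p = 0.0102). Shifted positions lack the preference of regions for promoters, so this does not show enrichment over other genes. The odds ratio of lincRNA genes was 1.23 and turned to 0.856 without piRNA genes in the background (adjusted Fisher p = 0.864). A scan of 175 gene name families, kept apart from the fixed lists, passed 20, of which 15 were enriched and 5 depleted. That count was 9 in the own list of replicate 1 and 4 in that of replicate 2.

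Region density was highest on chromosomes III, I and X and lowest on V. It was 32.2 regions per Mb on III, 29.9 on I, 29.5 on X, 26.3 on II, 19.5 on IV and 17.3 on V. The density on X was 1.22 times that on the autosomes (95% interval 1.10 to 1.34, exact binomial p = 8.85e-05), and per protein-coding gene it was 1.65 times (1.495 to 1.82). X also had 15.6 tRNA genes per Mb against 3.73 to 4.64 on the autosomes. Among regions more than 500 bp from any tRNA gene the X to autosome ratio was 1.01 (0.909 to 1.13, exact binomial p = 0.782), while per protein-coding gene it stayed at 1.38 (1.23 to 1.53, exact binomial p = 2.47e-08). The latter reflects gene number, with 2731 protein-coding genes on 17.7 Mb of X against 17242 on 82.6 Mb of autosomes. The share of tRNA genes with a region was 47.5% on X (131 of 276) and 49.7% on the autosomes (167 of 336), with a Fisher's exact p of 0.626. Along the autosomes, the density in the central of 3 equal segments was 1.10 times that in the outer segments (1.00 to 1.21, exact binomial p = 0.0389). With the left-out peaks added it was 1.09 and the call ended (exact binomial p = 0.0571). Per protein-coding gene the direction turned, to 0.895 (0.816 to 0.982, exact binomial p = 0.0188).

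**Figure D4:**
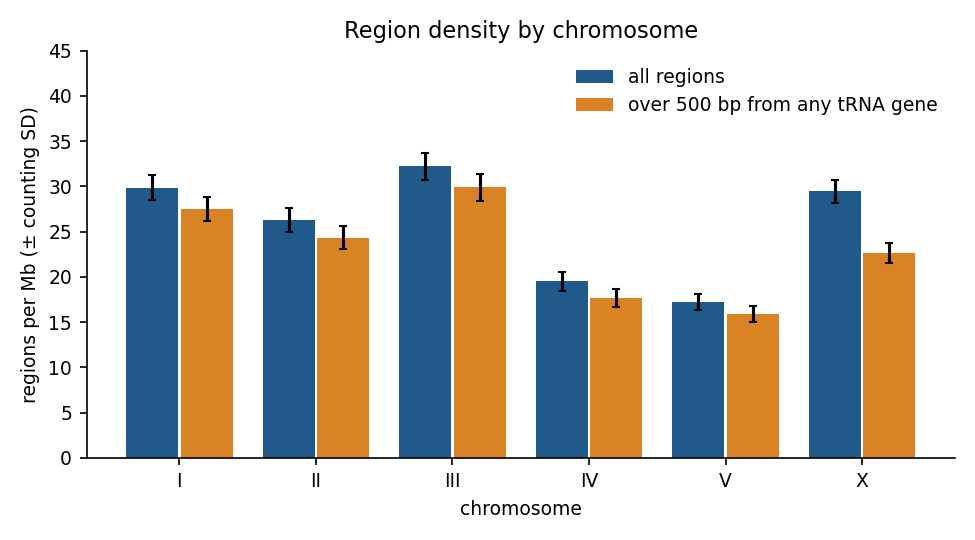
FLT-1 regions per Mb on each nuclear chromosome, for all regions (blue) and for regions more than 500 bp from any tRNA gene (orange), with error bars of 1 counting SD. The density on X was 29.5 for all regions and 22.6 away from tRNA genes.

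Promoter summits were GC-rich. Sequence within 100 bp of the 1043 promoter summits had a mean GC content of 44.8% ± 7.15 (SD). Control windows at the same distances from genes without a region had 34.7% ± 6.56 (SD over 10430 windows). The difference was 10.1 percentage points (9.69 to 10.6), with a permutation p of 1e-05, the smallest possible with 100000 resamples. The excess was centred on the summit, where mean GC content reached 53.0% against 34.4% in controls, and it was 7.42 points (6.88 to 7.95) against flanking sequence of the same promoters 400 to 600 bp away.

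**Figure D5:**
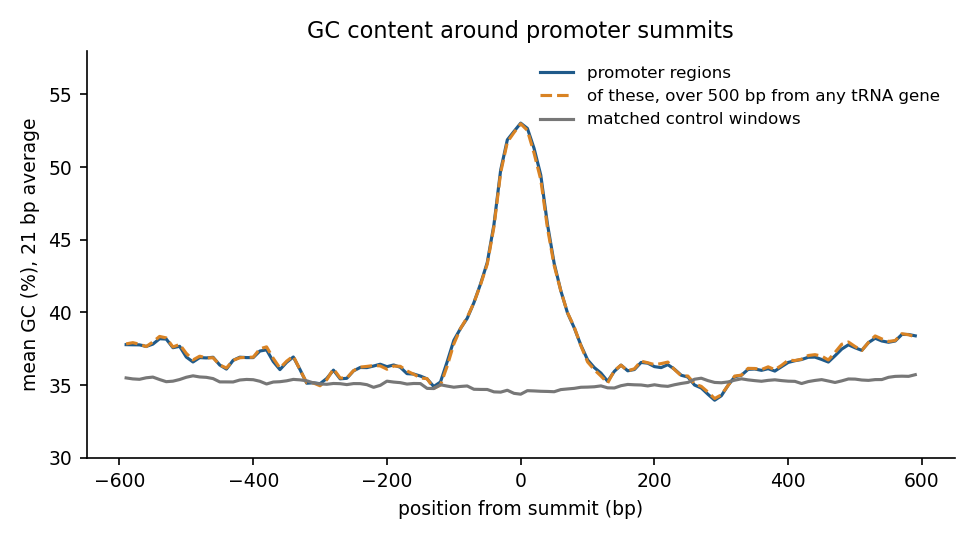
Mean GC content in percent, averaged over 21 bp, by position in bp from the summit for the 1043 promoter regions (blue), for those more than 500 bp from any tRNA gene (dashed orange) and for matched control windows (grey). Promoter regions reached 53.0% at the summit against 34.4% in controls.

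Of 24 fixed motifs, 7 were enriched and 8 depleted at promoter summits against controls at matched positions, and most of the depletions ended once controls were matched on GC content. These calls are by Fisher's exact test with Benjamini-Hochberg adjustment. The sequence CGCG occurred in 61.6% of promoter windows against 18.1% of control windows (odds ratio 7.25, adjusted Fisher p = 1.06e-185). The Sp1/KLF motif occurred in 15.1% against 3.06% (5.62, adjusted Fisher p = 6.03e-50), GAGAGA in 32.6% against 12.9% (3.27, adjusted p = 6.52e-53) and the E2F motif in 16.01% against 6.26% (2.85, adjusted p = 2.33e-24). CA repeats (odds ratio 4.08), the N-box of REF-1 and HES factors (1.65) and the runt motif (1.54) were also enriched. Depletion was seen for the motifs of SKN-1 (0.385), TCF/POP-1 (0.387), the SL1 splice acceptor (0.440), the TATA box (0.499), homeodomains (0.506), runs of T (0.516), GATA factors (0.582) and the heat shock element (0.717). With control windows matched on GC content (44.8% in 1041 regions and 44.7% in 2082 controls), 8 motifs remained past the threshold. CGCG was still in 61.7% against 32.8% (3.30, adjusted Fisher p = 4.02e-52), GAGAGA in 32.7% against 19.9% (1.95, adjusted p = 1.51e-13) and Sp1/KLF in 14.99% against 10.04% (1.58, adjusted p = 0.000346). The odds ratio of the E2F motif fell to 1.43 (adjusted Fisher p = 0.00384) and that of CA repeats to 1.85 (adjusted p = 0.00405). Depletion remained for TCF/POP-1 (0.568, adjusted Fisher p = 0.000119) and the SL1 splice acceptor (0.723, adjusted p = 0.00197). It ended for GATA factors (0.842, adjusted Fisher p = 0.0734), SKN-1 (0.820, adjusted p = 0.451), the TATA box (0.909, adjusted p = 0.675), homeodomains (1.23, adjusted p = 0.390) and the heat shock element (1.05, adjusted p = 0.763). The enrichment of the N-box (1.04, adjusted Fisher p = 0.763) and the runt motif (1.34, adjusted p = 0.0988) ended too. Runs of T turned from depleted to enriched there, with 25.5% against 18.8% (1.48, adjusted Fisher p = 0.000130). Among all 2080 6-mers, 1360 passed the threshold, 771 of them enriched and 589 depleted. With GC-matched controls 741 passed, and the balance turned to 310 enriched and 431 depleted. Among those past the threshold against position-matched controls and in at least 5% of promoter windows, the largest odds ratios were those of GCGCGC (10.9, in 16.5% of windows against 1.77%), CGCACG (7.89), CGCGCA (7.66), GCGCAC (7.63) and AGCGCG (7.55), and their odds ratios lay between 3.18 and 3.88 with GC-matched controls.

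The flt-1 gene itself (baz-2, WBGene00001470, III 7650553 to 7656032, minus strand) had a single peak within 2000 bp in the conservative list. The strain label places the insertion on chromosome I although flt-1 is annotated on III, and this conflict is not resolved here. The peak spanned III 7656544 to 7656839, with a summit 660 bp upstream of the gene start and a signal of 85.95, rank 1652 of 2633. The replicate signals were 37.0 in replicate 1 and 42.7 in replicate 2. The own list of replicate 1 instead held a peak inside the gene, at III 7655508 to 7655791 with a signal of 62.8, and that of replicate 2 held none within 2000 bp.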

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

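Peaks on the mitochondrial genome lie outside all comparisons of nuclear chromosomes, and they carry signal. The conservative list holds 22 mitochondrial peaks, and the own lists of the replicates hold 21 and 26. They cover 5330 bp (38.6%) of the 13794 bp genome, with a median pooled signal of 868 against 95.8 for nuclear peaks. Nearly every mitochondrial peak was kept: 22 of 23 ranked peaks (95.7%) are in the conservative list, against 2.71% of ranked nuclear peaks. The strongest region, M 5403 to 5879, had a summit 147 bp upstream of COX3, a subunit gene of cytochrome oxidase. Its pooled signal was 2189, and its mean replicate signal was 1014 ± 437 (SD, n = 2). The scaling of the signal, and how the authors' control file enters it, are not given. No input or untagged control list was analysed here, so whether this signal exceeds that of embryos without the tagged protein is unknown. No explanation was tested.

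A further 184 peaks past an IDR of 0.01 in the ranked list over both replicates are missing from the conservative list and were used only where a setting adds them back. Their median signal was 183, and 14 of the 20 strongest nuclear peaks of the ranked list are among them. The strongest, X 15810947 to 15811212 with a signal of 4659 and X 11785710 to 11785937 with 3234, exceed every region described in the report. None of the 184 lay within 200 bp of a tRNA gene. The deposited descriptions name 1 further file behind the thresholded lists without describing it, and the reason for leaving these peaks out is not given in the sources used here.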

How the results depend on the processing

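Depth is unknown, so what it limits could not be measured, and single-replicate lists come from each replicate's own IDR, a different kind of list. No paired analysis was possible because there is only 1 group. An IDR of at most 0.01 removes no peak and says nothing about stability. Promoter share, GC content at summits and the direction of the X ratio kept their direction and, except as given here, their side of the threshold under every alternative run. Values for an IDR of at most 0.0001, regions away from tRNA genes, left-out peaks, GC-matched controls and circular shifts come from alternatives chosen after seeing the data. For each value below the cause was not tested unless the setting itself shows it.

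The number of peaks was 1142 to 1543 without a replicate and 400 at an IDR of at most 0.0001, fewer by construction. The replicate 2 share in replicate 1 was 66.9% with 50% reciprocal overlap, 72.6% with summits within 100 bp and 80.7% at an IDR of at most 0.0001. The correlation was 0.921 on raw signal, 0.365 over all ranked peaks and 0.870 at an IDR of at most 0.0001. The X ratio fell to 1.01 away from tRNA genes. The centre to arm ratio was 0.895 per gene and 1.09 with left-out peaks (exact binomial p = 0.0571). The promoter to other signal ratio was 0.992 to 1.06 without a replicate and 0.818 at an IDR of at most 0.0001.

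At that stricter IDR 11 gene lists, 3 families and 578 6-mers passed. Families passing numbered 4 to 9 without a replicate, 12 with the nearest gene and 7 against genes with a ranked peak. With GC-matched controls 8 motifs and 741 6-mers passed, of which 557 6-mers passed in both. Near flt-1 there were 3 peaks in the other list, 0 in the replicate 2 list and 18, 17, 19 and 6 in the ranked lists, which have no threshold. Odds ratios of called sets that turned were collagens with the nearest gene (1.07), cyclins, CDKs and mitotic genes without replicate 1 (0.665, against 2.28 without replicate 2) and at the stricter IDR (0), tRNA genes away from tRNA genes (0.168, by construction), and the families cdk, lin, mrps, set and vps at the stricter IDR (0 each, with fewer regions). For motifs they were homeodomain (1.23), heat shock element (1.05) and T run (1.48) with GC-matched controls, and heat shock element at the stricter IDR (1.01). Against random positions, circular shifts passed 19 lists, 17 of them among the 22. Of the remaining values, 946 of single lists, families, motifs and regions were the same, 107 lost their call and 80 moved. The 946 include values that could not change, such as 22 lists and 20 families at an IDR of at most 0.01. They also include protein-coding lists under the background without piRNA genes, which leaves their odds ratios as they were.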

Other observations

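The scan of gene name families was fixed before the data were examined. Chosen after first results had been seen were the families and members named here, the settings away from tRNA genes and at an IDR of at most 0.0001, the counts at weak peaks and the tests of explanations, of which the test with left-out peaks was chosen after counts of those peaks were known. In the scan, the name families mdt, sec and cdk were among those enriched at genes with an FLT-1 region, while the families taf, with 3 of 17 genes, and rab, with 5 of 20, missed the threshold (adjusted Fisher p = 0.427 and 0.0724). Mediator genes (mdt), which link transcription factors to RNA polymerase II, had a region at 7 of 20 (odds ratio 7.40, 2.95 to 18.6, Fisher's exact test with adjusted p = 0.00437), led by mdt-9 with a signal of 106 ± 1.51 and mdt-26 with 103.6 ± 29.2 (SD, n = 2). In the own list of replicate 1 this call ended (5.41, adjusted Fisher p = 0.128) and in that of replicate 2 it stayed (14.8, adjusted p = 0.000152). It also ended with promoters from 500 bp upstream to 100 bp downstream (4.66, adjusted Fisher p = 0.142), with the single nearest gene start (2.85, adjusted p = 0.531), among genes with a ranked peak (4.67, adjusted p = 0.0550) and at an IDR of at most 0.0001 (9.28, adjusted p = 0.510). Genes of the sec family had a region at 6 of 19 (6.34, adjusted Fisher p = 0.0136), led by sec-15 with 311 ± 51.9 (SD, n = 2), whose region lies on a tRNA gene. Other members were sec-61.G and sec-61.B of the endoplasmic reticulum translocon with 100.6 ± 44.9 and 98.6 ± 40.02 (SD, n = 2). The call stayed in the own list of replicate 1 (7.74, adjusted Fisher p = 0.0409) and ended in that of replicate 2 (7.31, adjusted p = 0.126). It also ended away from tRNA genes (5.13, adjusted Fisher p = 0.0526), with the single nearest gene start (4.31, adjusted p = 0.183), among genes with a ranked peak (4.36, adjusted p = 0.107) and at an IDR of at most 0.0001 (9.83, adjusted p = 0.510). Cyclin-dependent kinases, of which cdk-4 and others also belong to a fixed list, had one at 5 of 11 (11.4, adjusted Fisher p = 0.00692), including cdk-9 with 82.3 ± 35.8 and cdk-7 with 80.8 ± 41.3 (SD, n = 2), both kinases of RNA polymerase II. That call ended in both replicate lists (8.11, adjusted Fisher p = 0.128, and 2.73, adjusted p = 1), among genes with a ranked peak (7.99, adjusted p = 0.0518) and at an IDR of at most 0.0001 (0, adjusted p = 1).

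Outside protein-coding promoters and more than 500 bp from any tRNA gene, regions were still assigned to 63 of the 113 snoRNA genes with a region, to 34 of 40 microRNA genes and to 14 of 26 snRNA genes. Among weak ranked peaks with an IDR above 0.5, 0.114% of 51067 regions lay at tRNA genes and 19.4% in promoters, against 0.272% and 21.4% of the genome.

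The X to autosome density ratio of 1.22 takes the autosomes together, and X lay within their range, so no excess particular to X was shown. This ratio was weighed against 2 technical explanations. With the 184 left-out peaks added back it was 1.21 (1.10 to 1.33), but these peaks add 178 regions, which could not have brought the interval to 1 even if all lay on autosomes (1.12, 1.01 to 1.23), so this test decides nothing about the selection of peaks. Without regions within 500 bp of a tRNA gene it was 1.01 (0.909 to 1.13), as predicted if the density of tRNA genes on X accounts for it. The higher number of tRNA genes on X is thus a candidate explanation for the excess per Mb, found and tested on the same data, but not for that per protein-coding gene, which was 1.38 (1.23 to 1.53) away from tRNA genes, a setting added last. No biological explanation was tested, because there is only 1 group.

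The GC excess of 10.1 percentage points at promoter summits could come from tRNA genes inside promoters or from libraries that favour GC-rich sequence. Away from tRNA genes the difference was 10.1 (9.70 to 10.6), which argues against tRNA genes. At 2000 promoter peaks with an IDR above 0.5 it was 0.622 (0.282 to 0.936), which argues against a GC preference present at any weak peak. A GC preference that acts on strong peaks alone, and GC-rich sequence at open promoters in general, stay open, since no input list was analysed here. No biological explanation was tested.

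The regions at tRNA and ribosomal protein genes may reflect signal along transcribed genes or reads shared between identical tRNA copies. At ribosomal protein genes 1 of 42 summits (2.38%, 0.422 to 12.3) lay in the gene body, which argues against signal along these gene bodies, while at tRNA genes most summits lay inside the gene and this stays open. A region was found at 51 of 143 single-copy tRNA genes (35.7%) and at 247 of 469 with identical copies (52.7%), a ratio of 0.677 (0.515 to 0.834). This lies above the 0.5 set as the bound, which argues against shared reads as the whole cause, but the lower share leaves a part open. Signal that any tagged protein gives at highly transcribed genes stays open, and no biological explanation was tested.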
